A study of Mus musculus with 9 samples.

How the data were processed

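RNA was sequenced in 9 samples of mouse neural stem cells, 3 treated with NAT, 3 with P7C3-A20 and 3 with the DMSO vehicle, and libraries were built with an Illumina TruSeq RNA kit, per the labels' protocols. The kit is not stated there to mark the strand, so reads of overlapping or antisense genes cannot be told apart. The deposited table gives TPM, transcript abundances scaled to the same total, for 23420 gene symbols in 9 columns, which the authors made by dividing reads by a gene length and scaling each library, since every column sums to 1000000. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm9 without a role or an order. The read counter, the annotation and any filter on reads are not given in the sources used here. For that reason no coordinates are given. In the gene names, 27 entries had been turned into dates and were left as they stood.

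The TPM of weakly expressed genes rise in steps of 1 read, so whole read numbers were recovered from these steps for 19300 of the 19302 genes with any value (99.99%), with a tolerance of 0.001. In simulated data for 18733 genes, 96.40% were recovered exactly, and 100% when multiples by a common divisor were counted too. Recovered reads came to 12310912, 11387644 and 13514399 in DMSO replicates 1, 2 and 3, to 12661869, 13419458 and 12610526 in the NAT replicates and to 15606533, 16821164 and 15291621 in the P7C3-A20 replicates. These reads set the depth and entered only the alternatives that need counts. Rn45s and Malat1 were not recovered.

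The choice of test had been written for counts and for normalised values before the data were examined, and the one for normalised values was used because the table holds TPM. Groups were compared with limma-trend on log2(TPM + 1) over 13839 genes with a TPM of at least 1 in at least 3 libraries. All 9 libraries entered 1 fit with the group as the only factor, which left 6 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg, and a gene was called below an adjusted p of 0.05 with no minimum fold. Errors of log2 fold changes are the fit's standard errors, and intervals are 95% intervals. Tests used limma 3.58.1 in R 4.3.3. Other steps and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The labels call the libraries of a group biological replicates without saying whether these were separate cultures or animals, so p-values measure the spread between these libraries.

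A set of 31 gene lists, covering brain cell types, cell division, metabolism, stress responses and signalling, was fixed before the data were examined. The 28 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, against all other genes and with adjustment over the lists. Camera was repeated with a correlation estimated for each list. As an addition, each list was reduced to 1 score per library, the mean of its members. The scores were compared with limma, which also gave the intervals of list means. They were not set against the other genes, so they hold any shift of all genes between groups. Lists are described where the camera adjusted p was below 0.1 in that comparison.

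The rule for named genes was also fixed before the data were examined. It took the 10 highest and 10 lowest called genes per comparison with no overlap between the groups and a mean of at least 2 TPM in a group, for NAT against P7C3-A20 the 5 highest and 5 lowest. Since fewer passed, it was filled to 10 with the genes of lowest p, which missed the threshold. It added up to 4 members of lowest p from each described list, and Nampt. Genes outside the rule are said to have been chosen after their values were seen.

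GC content and length were those of the longest GENCODE mouse transcript of each symbol (assembly GRCm38). Symbols not found there were looked up among the synonyms of the RefSeq gene table. Together these matched 98.3% of the names. Of the tested genes, 13701 had a GC content, as did all 511 list members among them. Alternatives written before the data were examined were the replicate number as a block, quantile normalization, robust empirical Bayes, no filter or a minimum of 5 TPM, a pseudocount of 0.1, a minimum log2 fold change of 1, the 6 compared libraries alone, and each library left out. Chosen after seeing the data were voom on the recovered reads, a minimum of 10 reads, removal of each library's trend with GC content (a spline with 5 degrees of freedom) or with GC content and length, the list scores and reads thinned to the shallowest library. The fits were tested on simulated data with 200 changed genes for NAT against DMSO over 13729 genes, where limma-trend called 46% of the 1.25-fold changes, 92% of the 1.5-fold changes and 94% of the 2-fold changes. For P7C3-A20 against DMSO, over 13717 genes, these shares were 56%, 92% and 92%. For NAT against P7C3-A20, over 13725 genes, they were 46%, 94% and 94%. The simulated genes varied independently and without a GC trend, and their spread beyond counting was set from well counted genes. The real libraries differed in GC trend, so these shares may be too high for them, and genes not called may still have changed. No library or column was left out of the tests. Removing a library's trend with GC content, or with GC content and length, also took out its overall shift over the genes.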

Results

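Neural stem cells were taken from the hippocampus of 2-day-old C57BL/6J mice and grown in culture. The medium was then changed to one without the growth factors bFGF and EGF, which lets the cells differentiate. In that medium the cells received 3 µM NAT, described in the labels as a new small molecule, 3 µM P7C3-A20 or the vehicle DMSO, with 3 libraries in each group. P7C3-A20 is an aminopropyl carbazole known to favour the survival of newborn neurons and reported to act on NAMPT, the rate-limiting enzyme of NAD salvage. Gene expression was measured by RNA sequencing, at 11387644 to 13514399 recovered reads in the DMSO and NAT libraries and 15291621 to 16821164 in the P7C3-A20 libraries. The comparisons asked which genes each compound changed against the vehicle and where the compounds differed from each other at the same dose.

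With DMSO, the cultures expressed genes of neural progenitors, glia and neurons together. The radial glial fatty acid binding protein gene Fabp7 reached 12200 ± 292 TPM (SD, n = 3) and the intermediate filament gene Vim 3791 ± 48.3 TPM. Among astrocyte genes, Cst3 stood at 6928 ± 455 TPM and Apoe at 6163 ± 411 TPM. The oligodendrocyte lineage factors Olig1 and Olig2 were at 2158 ± 50.6 and 824 ± 15.8 TPM, and the neuronal cytoskeleton genes Tubb2b and Map2 at 1028 ± 23.1 and 640 ± 13.7 TPM. Top2a, a topoisomerase of dividing cells, was at 244 ± 22.8 TPM. Of the microglia and macrophage genes, Cd68 reached 7.29 ± 0.831 TPM, while Cx3cr1, C1qc, Trem2 and Ctss were listed at 0. The haemoglobin genes of the blood list were listed at 0 as well. These examples were among the most abundant or the absent members of the fixed lists, chosen after their values were seen.

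The libraries differed in how gene levels followed GC content. In units of log2 per 10 percentage points of GC, over 11281 genes, the slopes were -0.056, -0.0232 and -0.0044 in DMSO replicates 1, 2 and 3, and -0.0661, 0.0038 and -0.0314 in the NAT replicates. They were 0.0165, 0.0384 and 0.122 in the P7C3-A20 replicates, the highest in P7C3-A20 replicate 3. Across genes, which are not independent replicates, the fold change followed GC content with a Spearman rho of 0.011 for NAT against DMSO, 0.555 for P7C3-A20 against DMSO and -0.547 for NAT against P7C3-A20. The row of the ribosomal RNA precursor Rn45s held 20260 ± 2624 TPM with DMSO, 11200 ± 2414 TPM with NAT and 12420 ± 3885 TPM with P7C3-A20, a gene chosen after its values were seen.

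**Figure D1:**
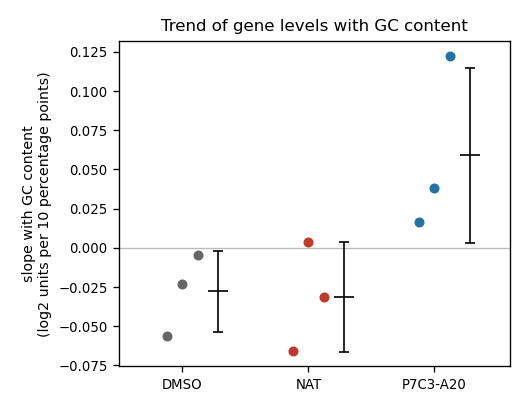
Slope of gene levels with GC content in each of the 9 libraries (log2 units per 10 percentage points of GC), by group, over 11281 genes. The 3 P7C3-A20 libraries lie highest, between 0.0165 and 0.122, and the others between -0.0661 and 0.0038.

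Immediate early genes, the transcription factors and signalling genes that cells switch on first after a stimulus, fell with NAT. The AP-1 subunit gene Fosb fell from 129 ± 17.2 TPM with DMSO to 73.8 ± 4.91 TPM with NAT (SD, n = 3), a log2 fold change of -0.80 ± 0.10 (SE) with a limma adjusted p of 0.0234. Btg2, an antiproliferative gene induced by p53 and by growth factors, fell from 157 ± 9.15 to 120 ± 3.98 TPM, a log2 fold change of -0.38 ± 0.04 with an adjusted p of 0.0142. Every NAT library lay below every DMSO library for both genes. The list of 17 measured immediate early genes fell as a group, with 15 members negative, a mean log2 fold change of -0.26 (95% interval -0.39 to -0.14) and a camera adjusted p of 1.362e-15. The list had an adjusted p of 0.0580 with an estimated correlation, and an adjusted p of 0.0187 when reduced to 1 score per library.

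Within that list, 11 genes fell when adjusted over the list alone and 2 over all genes tested. Ier2, a nuclear immediate early protein gene, went from 153 ± 15.1 to 115 ± 8.05 TPM (-0.41 ± 0.07), and Egr3, a zinc finger factor, from 12.2 ± 2.24 to 7.85 ± 0.362 TPM (-0.56 ± 0.11). The other 7 that passed within the list were Jun, Fos, the orphan nuclear receptor gene Nr4a1 (-0.51 ± 0.14), Klf4, Myc, Junb and Egr2, named after their values were seen. Dusp1, Arc, Fosl2, Atf3, Klf2 and Egr1 did not pass, and Egr1 had a log2 fold change of -0.01. Fosb kept its call without DMSO replicate 2, while without DMSO replicates 1 and 3 and NAT replicates 1, 2 and 3 its adjusted p was 0.0917, 0.0708, 0.0811, 0.130 and 0.0906. For Btg2 the adjusted p was 0.0731 without DMSO replicate 1, 0.0648 without DMSO replicate 3, 0.0806 without NAT replicate 2 and 0.0906 without NAT replicate 3.

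**Figure D2:**
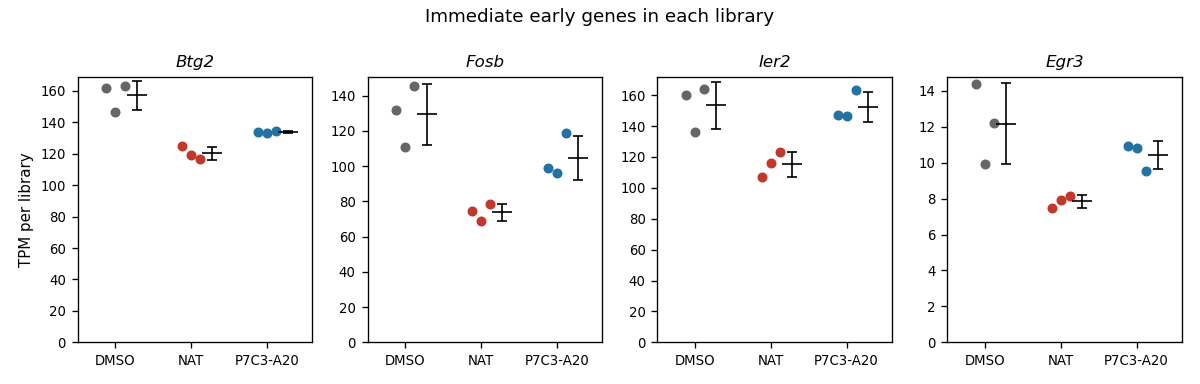
TPM of immediate early genes in each library, by group, with the mean and SD of the 3 libraries. Fosb lies at 73.8 TPM with NAT, against 129 TPM with DMSO and 105 TPM with P7C3-A20.

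Proliferation genes were higher with NAT than with DMSO in 33 of 35 cases, with a mean log2 fold change of 0.11 (0.01 to 0.20) and a camera adjusted p of 5.059e-05. The list had an adjusted p of 0.657 with an estimated correlation and 0.155 as 1 score per library. Of its members 3 rose adjusted over the list alone, and none over all genes: the cyclin gene Ccne1 (0.27 ± 0.06), the ribonucleotide reductase subunit gene Rrm2 (0.27 ± 0.07) and the mitotic transcription factor gene Foxm1 (0.15 ± 0.04). Mcm3, part of the replicative helicase, was at 0.22 ± 0.07 and did not pass. Without DMSO replicate 3 the camera adjusted p of the list was 0.316.

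Targets of NRF2, the regulator of the oxidative stress response, also rose with NAT. Of 18 measured, 16 were positive, with a mean of 0.10 (0.04 to 0.15) and a camera adjusted p of 5.302e-05. The list had an adjusted p of 0.0515 with an estimated correlation and 0.0330 as 1 score per library. The mean and the score hold a shift of all genes between these groups, whose median log2 fold change was 0.03. With the GC trend and this shift removed the mean was 0.07. The estimated correlation was 0.008, under the preset 0.01, while the unadjusted camera p rose from 5.68e-06 to 0.003679. A count of 7 rose adjusted over the list alone, and none over all genes tested. The examples were the glutathione transferase gene Gstm1 (0.20 ± 0.04), the sulfiredoxin gene Srxn1 (0.27 ± 0.06), Gclc, the catalytic subunit of glutathione synthesis (0.20 ± 0.04, 49.5 ± 0.894 to 56.9 ± 0.640 TPM), and the ferritin gene Fth1 (0.12 ± 0.03).

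Lineage genes moved in different directions with NAT. Oligodendrocyte lineage genes fell as a list, with 15 of 20 negative, a mean of -0.06 (-0.14 to 0.03) and a camera adjusted p of 1.25e-04, but an adjusted p of 0.388 with an estimated correlation and 0.296 as 1 score per library. In this list 2 genes fell adjusted over the list alone and none over all genes: Sox10, the factor that specifies the lineage (-0.24 ± 0.06), and Gpr17, a receptor of immature oligodendrocytes (-0.34 ± 0.08). Cnp (-0.10 ± 0.04) and Pdgfra (-0.12 ± 0.06) did not pass. Neuroblast and neuron genes fell as a list, with 23 of 30 negative, a mean of -0.07 (-0.13 to -0.02) and a camera adjusted p of 1.842e-04. The list had an adjusted p of 0.0515 with an estimated correlation and 0.155 as 1 score per library. Its estimated correlation was -0.004, which is also under the preset 0.01. No member passed adjusted over the list alone or over all genes; Stmn3 was at -0.17 ± 0.06, the synaptic Snap25 at -0.16 ± 0.06 and the calretinin gene Calb2 at -0.45 ± 0.19. Astrocyte genes rose as a list, with 22 of 24 positive, a mean of 0.10 (0.01 to 0.18) and a camera adjusted p of 6.572e-04, but an adjusted p of 0.657 with an estimated correlation and 0.155 as 1 score per library. No astrocyte gene passed adjusted over the list alone or over all genes, and the filament gene Gfap went from 821 ± 76.4 to 967 ± 55.3 TPM (0.24 ± 0.07), S100b was at 0.15 ± 0.05, Mlc1 at 0.11 ± 0.03 and Slc4a4 at 0.23 ± 0.07.

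The Notch list fell by camera, with an adjusted p of 0.0398, an adjusted p of 0.657 with an estimated correlation and 0.223 as 1 score per library. Its mean was -0.06 (-0.12 to 0.01) while its median was 0.02, since 7 of 13 members were positive. The 3 genes that fell adjusted over the list alone, none of which passed over all genes, were the Notch effector genes Hes5 (-0.34 ± 0.07, 155 ± 15.2 to 122 ± 5.22 TPM) and Hes1 (-0.25 ± 0.06) and the ligand gene Dll3 (-0.23 ± 0.07). Notch3 was at 0.16 ± 0.06 and did not pass. The call was lost without DMSO replicate 2 (camera adjusted p 0.0866), DMSO replicate 3 (0.246) or NAT replicate 1 (0.289).

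Fatty acid synthesis genes rose as a list, with 13 of 14 positive, a mean of 0.08 (-0.005 to 0.168), a camera adjusted p of 0.0130, an adjusted p of 0.657 with an estimated correlation and 0.191 as 1 score per library. Malic enzyme Me1 rose adjusted over the list alone (0.24 ± 0.05), and over all genes none did; Fads1 and Gpam were both at 0.12 and Acaca at 0.12 ± 0.05. The adjusted p was 0.0530 without DMSO replicate 2, 0.0502 without NAT replicate 2 and 0.0667 with the trends with GC content and length removed. With the GC trend alone removed the camera adjusted p was 0.0286 and the mean 0.05. That removal also took out the shift of all genes between these groups, whose median went from 0.03 to 0.002. Oxidative phosphorylation genes had 23 of 32 members negative, a mean of -0.02 (-0.07 to 0.03) against a median of 0.03 for all genes, a camera adjusted p of 2.121e-04, an adjusted p of 0.431 with an estimated correlation and 0.445 as 1 score per library. Its lowest p-values belonged to Ndufv1, Ndufa4, Ndufb5 and Cox6c, at -0.07, -0.07, -0.06 and -0.05, and none passed adjusted over the list alone or over all genes. Endoplasmic reticulum chaperones missed the threshold, with a camera adjusted p of 0.0597, 14 of 18 members positive and a mean of 0.05.

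In all, camera called 9 lists and limma 4 genes for NAT against DMSO. The 4 genes were all lower, and 1615 genes had an unadjusted p under 0.05. Besides Fosb and Btg2 these were the microRNA genes Mir149 and Mir365-2, the latter outside the rule for named genes. Each had 1 read in every DMSO library and was listed at 0 in the 6 others, so no fold is given. Among the genes that missed the threshold, Cacng5, an AMPA receptor auxiliary subunit, went from 57.0 ± 1.30 to 69.7 ± 3.92 TPM (0.29 ± 0.04), the neuroendocrine Ptprn from 47.0 ± 0.887 to 57.6 ± 3.19 TPM (0.29 ± 0.05), and Cyp46a1, the cholesterol 24-hydroxylase of brain, from 29.5 ± 1.97 to 38.2 ± 1.24 TPM (0.36 ± 0.06). Mir1898 was at 0.79 ± 0.12, Sh3pxd2b at 0.22 ± 0.04 and Rpl35 at -0.18 ± 0.03. Rpph1, the RNA of ribonuclease P, held 33.3 ± 3.97 TPM with DMSO and 16.4 ± 4.44 TPM with NAT. The groups did not overlap for 1955 genes higher and 677 lower with NAT, 19.0% of the genes where chance gives 10%. The median log2 fold change of all genes was 0.03, against 0.002 with quantile normalization and -0.003 in voom. Part of the excess of higher genes may be this shift. The list means, intervals, counts of positive members and adjusted p-values of the scores for NAT against DMSO hold it too. Camera instead compared each list with the other genes. The count of called genes was 11 without DMSO replicate 2 and 1 without DMSO replicate 3 or without NAT replicate 3, and voom on the recovered reads, chosen after seeing the data, called 29, but 12 without DMSO replicate 1, 14 without DMSO replicate 2, 12 without NAT replicate 2 and 11 without NAT replicate 3. It called 37 without DMSO replicate 3 and 26 without NAT replicate 1. The 29 were 7 higher and 22 lower, and with the GC trend removed voom called 58, 24 higher and 34 lower, or 12 to 84 with a library left out.

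C1ql1, which encodes a secreted C1q-like synaptic protein, rose with P7C3-A20 from 48.1 ± 2.00 TPM with DMSO to 63.0 ± 2.64 TPM (SD, n = 3). The log2 fold change was 0.38 ± 0.05 (95% interval 0.27 to 0.49) with a limma adjusted p of 0.0484, and all 3 P7C3-A20 libraries lay above the DMSO libraries. The other genes called were Mir149 and Mir365-2, with the same single reads in the DMSO libraries and 0 here. These 3 genes, 1 higher and 2 lower, stood beside 2194 with an unadjusted p under 0.05. C1ql1 was at 0.27 with an adjusted p of 0.230 once the GC trend was removed, its adjusted p was 0.0781 to 0.104 with the 6 compared libraries alone, a minimum of 5 TPM, no filter or a pseudocount of 0.1, and without DMSO replicates 1 and 2 and P7C3-A20 replicates 1, 2 and 3 its adjusted p was 0.222, 0.121, 0.157, 0.216 and 0.0712. Without DMSO replicate 3 the count was 10, without any 1 of P7C3-A20 replicates 1, 2 and 3 it was 1, and voom on the recovered reads called 284, or 41 with the GC trend removed, which became 0 and 1 without DMSO replicate 1 and 8 and 4 without DMSO replicate 2. Without any other single library voom called 195 to 591, and 14 to 157 with the GC trend removed.

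Among genes that missed the threshold with P7C3-A20, the receptor kinase gene Tyro3 went from 77.1 ± 1.66 to 89.6 ± 2.30 TPM (0.21 ± 0.04). The signal regulatory protein gene Sirpa was at 0.25 ± 0.04, the calmodulin kinase subunit gene Camk2b at 0.19 ± 0.03 and Igfbp4, which binds insulin-like growth factors, at 0.28 ± 0.05, from 113 ± 5.44 to 138 ± 6.79 TPM. Cacng5 was at 0.25 ± 0.04, Uckl1 at 0.29 ± 0.05 and Cpxm1 at 0.29 ± 0.05. The small nucleolar RNA gene Snord99 had 0 to 1 reads in the DMSO libraries and 6 to 7 in the P7C3-A20 libraries. Fosb was at -0.30 ± 0.10 with an adjusted p of 0.203 and Btg2 at -0.23 ± 0.04 with an adjusted p of 0.140, both added after their values were seen. The groups did not overlap for 1819 genes higher and 1037 lower, 20.6% of the genes where chance gives 10%. Part of this excess may follow the GC trend, and overlap was not counted with it removed. With that trend removed, 1511 of 13701 genes had an unadjusted limma p under 0.05, against 2194 of 13839 before. The median log2 fold change of all genes was 0.015, and -0.004 with quantile normalization.

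No gene list passed with P7C3-A20 by camera, with an estimated correlation or by list scores, while 5 had an unadjusted camera p under 0.05. Oligodendrocyte lineage genes had 18 of 20 positive, a mean of 0.14 (0.06 to 0.23), a camera adjusted p of 0.0515 and an adjusted p of 0.893 with an estimated correlation. With the GC trend between these libraries removed, their mean was 0.09 and the camera adjusted p 0.378. No member passed adjusted over the list alone or over all genes; the myelin regulatory factor gene Myrf went from 8.37 ± 0.953 to 11.3 ± 0.976 TPM (0.39 ± 0.11), Nkx6-2 was at 0.33 ± 0.10 and Bcas1 at 0.36 ± 0.14. Proliferation genes had 21 of 35 negative, a mean of -0.04 (-0.14 to 0.05), the same camera adjusted p of 0.0515 and the same adjusted p of 0.893 with an estimated correlation. The mitotic genes Cenpf, Nusap1, Mki67 and Kif11 were at -0.21, -0.22, -0.20 and -0.16, and none passed adjusted over the list alone. Astrocyte genes had 18 of 24 positive, a mean of 0.05, a camera adjusted p of 0.0874 and an adjusted p of 0.893 with an estimated correlation, and with the GC trend removed their mean was 0.02 and the camera adjusted p 0.462. Among them 3 rose adjusted over the list alone, and none over all genes: Ttyh1 (0.17 ± 0.04), the neurotensin receptor gene Ntsr2 (0.27 ± 0.07) and the clusterin gene Clu (0.17 ± 0.05), of which Clu did not pass with the GC trend removed (0.10). Without DMSO replicate 3 the number of lists passing was 5, without P7C3-A20 replicate 3 it was 4, and it was 2 without DMSO replicate 2 or without P7C3-A20 replicate 1. With the GC trend removed camera called 2 lists lower, proliferation (mean -0.05, adjusted p 0.0156) and immediate early (mean -0.11, adjusted p 0.00997). Before that removal the immediate early mean with P7C3-A20 was -0.05 (-0.17 to 0.08), with a camera adjusted p of 0.251.

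Compared directly at 3 µM, NAT and P7C3-A20 differed in 5 gene lists by camera, of which proliferation and oligodendrocyte lineage genes had the lowest p. All 35 proliferation genes were higher with NAT than with P7C3-A20, with a mean log2 difference of 0.15 (95% interval 0.05 to 0.25) and a camera adjusted p of 2.349e-10. The list had an adjusted p of 0.503 with an estimated correlation and 0.0381 as 1 score per library. A total of 16 were higher adjusted over the list alone and 0 over all genes, among them the spindle motor gene Kif11 (83.4 ± 3.85 against 69.1 ± 4.36 TPM, SD, n = 3, 0.27 ± 0.06), the kinetochore gene Cenpf (0.27 ± 0.06), Top2a (259 ± 8.82 against 220 ± 11.6 TPM, 0.24 ± 0.06) and the checkpoint kinase gene Bub1 (0.23 ± 0.06). All 20 oligodendrocyte lineage genes were lower with NAT, with a mean of -0.20 (-0.28 to -0.11), a camera adjusted p of 3.127e-09, an adjusted p of 0.178 with an estimated correlation and 0.0112 as 1 score per library. Of these 8 were lower adjusted over the list alone and 0 over all genes, with Sox10 at 50.6 ± 1.81 against 63.3 ± 2.76 TPM (-0.32 ± 0.06), Gpr17 at 61.8 ± 5.38 against 80.3 ± 7.12 TPM (-0.37 ± 0.08) and Myrf at -0.41 ± 0.11. The GC trend also differed between these libraries, and with it removed the list means were 0.13 and -0.18.

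Immediate early genes were lower with NAT than with P7C3-A20 as well. Of 17 measured, 15 were negative, with a mean of -0.22 (-0.34 to -0.10) and a camera adjusted p of 4.721e-09. The list had an adjusted p of 0.210 with an estimated correlation and 0.0232 as 1 score per library. With the GC trend removed the mean was -0.18 and the camera adjusted p 3.915e-07. Adjusted over the list alone 10 were lower and over all genes 0: Ier2 was at -0.40 ± 0.07, Fosb at -0.50 ± 0.10 (-0.71 to -0.28), Nr4a1 at -0.60 ± 0.14 and Junb at -0.38 ± 0.09. NRF2 targets were higher with NAT in 17 of 18 cases, with a mean of 0.11 (0.05 to 0.16), a camera adjusted p of 5.173e-05, an adjusted p of 0.109 with an estimated correlation and 0.0169 as 1 score per library. Adjusted over the list alone 6 were higher and over all genes 0, including Gstm1 (0.22 ± 0.04), Gsta4 (0.16 ± 0.03), the quinone reductase gene Nqo1 (0.31 ± 0.06) and Gclc (0.17 ± 0.04). The Notch list was lower with NAT, with 11 of 13 negative, a mean of -0.08 (-0.14 to -0.01), a camera adjusted p of 0.0143, an adjusted p of 0.503 with an estimated correlation and 0.128 as 1 score per library. Of its members Dll3 (-0.33 ± 0.07) was lower adjusted over the list alone and none over all genes, and Hes5 stood at -0.22 ± 0.07. The Notch call was lost without NAT replicate 1 (camera adjusted p 0.0651) and with the GC trend removed (0.181). Fatty acid synthesis genes (mean 0.07, camera adjusted p 0.0588, or 0.0269 with the GC trend removed) and neuroblast and neuron genes (mean -0.06, camera adjusted p 0.0997) missed the threshold.

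**Figure D3:**
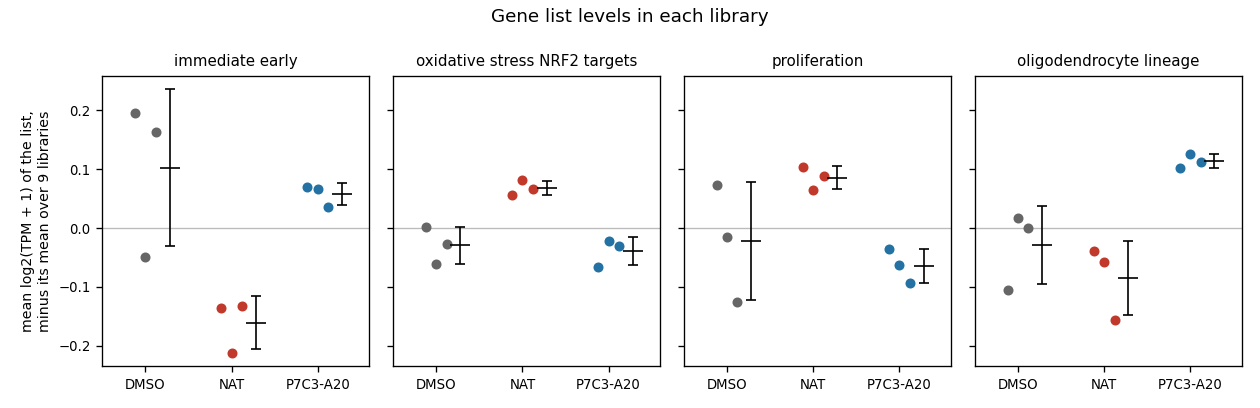
Mean log2(TPM + 1) of gene lists in each library, relative to the list's mean over the 9 libraries, by group. The oligodendrocyte lineage list lies lower with NAT than with P7C3-A20 by a mean of -0.20, and the proliferation list higher by 0.15.

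No single gene differed between the compounds by limma, although 2188 had an unadjusted p under 0.05, and voom on the recovered reads called 347, or 73 with the GC trend removed. These counts rested on single libraries, with 9 and 6 called without NAT replicate 1, 177 and 1 without NAT replicate 2, 24 and 11 without NAT replicate 3, 834 and 159 without P7C3-A20 replicate 1, 336 and 43 without P7C3-A20 replicate 2 and 90 and 53 without P7C3-A20 replicate 3. The lowest p-values belonged to Aspdh (-0.43 ± 0.06, 17.1 ± 1.08 TPM with NAT against 23.3 ± 1.00 with P7C3-A20), to Haus6 of the augmin complex of the spindle (0.36 ± 0.05, 20.6 ± 0.432 against 15.9 ± 0.417 TPM) and to the histone gene Hist2h2ac, which had 0 to 5 reads per library and near-identical family members. C1ql1 was at -0.30 ± 0.05, the tubulin gene Tubb4a at -0.31 ± 0.05, Amdhd2 at -0.24 ± 0.04, the nuclear import receptor gene Tnpo1 at 0.22 ± 0.04 and the chromatin factor gene Atad2 at 0.47 ± 0.08. The groups did not overlap for 1843 genes higher and 1155 lower with NAT, 21.7% of the genes where chance gives 10%. Here too part of the excess may follow the GC trend. With that trend removed, 1605 of 13701 genes had an unadjusted limma p under 0.05, against 2188 of 13839 before. The median log2 difference of all genes was 0.011, and 0.001 with quantile normalization.

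Nampt and the other tested genes of NAD synthesis and use did not pass over all genes by limma in any comparison. Nampt stood at 19.0 ± 0.703 TPM with DMSO, 20.9 ± 1.84 TPM with NAT and 19.6 ± 0.234 TPM with P7C3-A20 (SD, n = 3). Its log2 fold change was 0.13 ± 0.07 (-0.01 to 0.28, adjusted p 0.453) with NAT and 0.05 ± 0.07 (adjusted p 0.759) with P7C3-A20. The difference between the compounds was 0.09 (-0.06 to 0.23, adjusted p 0.541) and turned to -0.003 with the GC trend removed. Over the 21 measured genes of the list, the mean was 0.04 with NAT (camera adjusted p 0.944, where camera placed the list lower than other genes) and 0.05 with P7C3-A20 (0.518). The deacetylase gene Sirt2, chosen after its values were seen, rose with P7C3-A20 adjusted over the list alone (0.17 ± 0.04) and in voom over all genes (adjusted p 0.0466), and with the GC trend removed it passed neither over the list (0.11) nor in voom (adjusted p 0.255). Aryl hydrocarbon receptor targets were too few to test, with Nfe2l2 at 132, 140 and 131 TPM, Tiparp at 50, 49.4 and 45 TPM and Cyp1b1 at 2.13, 2.33 and 2.48 TPM with DMSO, NAT and P7C3-A20, and the other 4 below 1 TPM in every library.

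The responses to the compounds shared the 3 DMSO libraries. Their log2 fold changes had a covariance of 0.0156 across 13839 genes, where 100 simulations of unchanged groups against the same controls gave 0.0117 (SD 0.000896), a difference of 0.00385. The Pearson r across genes was 0.509 against 0.5 in the simulations, and 63.6% of genes had the same sign against 66.7%. With a minimum of 10 reads in 3 libraries the difference in covariance was 0.00136, and r was 0.444 against 0.5. Of the genes called by limma, Mir149 and Mir365-2 were called lower in both comparisons. The 3 control libraries were too few to divide, so part of any excess may come from the shared controls.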

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

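The GC correction, the GC and length correction, the thinning of reads, the list scores, voom, the mean expected from GC content, the counts of splits that called a given list and the single-read test of the microRNA genes were chosen only after the results were seen. In the direct test between the compounds, camera called 5 gene lists, of which 4 also differed as 1 score per library, and none passed with an estimated correlation. For these 4 the mean log2 differences, NAT minus P7C3-A20, were -0.198 for oligodendrocyte lineage genes, 0.15 for proliferation genes, 0.107 for NRF2 targets and -0.218 for immediate early genes. No outlier test was run on groups of 3, but P7C3-A20 replicate 3 stood apart from replicates 1 and 2 of its group. The recovered reads of these pairs differed with a chi-square per degree of freedom of 4.75 and 4.19, against 1.36 to 2.40 for all other pairs within a group, and the replicate also had the highest slope with GC content. Without it the differences between the compounds were 0.135 for proliferation and -0.199 for oligodendrocyte lineage genes.

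Immediate early genes lay below DMSO with NAT by a mean of -0.263 ± 0.081 (SE between libraries). Over all genes the fold change hardly followed GC content (Spearman rho 0.011), which itself argues against a GC trend as the whole cause. The mean expected for the members from that trend, -0.00135 relative to all genes, was therefore bound to be small and is no separate test. A trend with transcript length is argued against as the whole cause by a mean of -0.288 after the trends with GC content and length were removed. That removal took the Spearman rho of fold change with length from 0.216 to 0.048. One control library alone is argued against as well, since the mean was -0.217 without DMSO replicate 1, -0.340 without DMSO replicate 2 and -0.233 without DMSO replicate 3. The ERK feedback list, a readout of a pathway known to induce these genes, did not fall with NAT, with a mean of 0.063 (0.002 to 0.124) and a camera adjusted p of 0.113, so no source of the lower values within the cells is proposed. A difference in handling at harvest, to which immediate early genes are known to respond, was not tested, since the labels give no harvest order.

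Proliferation genes lay higher and oligodendrocyte lineage genes lower with NAT than with P7C3-A20, in libraries that also differed in GC trend and depth. With the GC trend removed the means were 0.128 ± 0.014 and -0.175 ± 0.046, and with reads thinned to the shallowest library 0.14 ± 0.020 and -0.179 ± 0.039, which argues against either as the whole cause. The smallest means with 1 P7C3-A20 library left out were 0.135 for proliferation and -0.192 for the oligodendrocyte lineage. The values are consistent with cultures that held more dividing cells and fewer oligodendrocyte lineage cells with NAT, or with changed expression per cell, and bulk RNA does not separate these. With an estimated correlation between genes neither list passed (adjusted p 0.503 and 0.178), and how much came from either compound is open, with intervals against DMSO of 0.013 to 0.203 with NAT and -0.137 to 0.053 with P7C3-A20 for proliferation, and -0.141 to 0.030 and 0.058 to 0.228 in the same order for the oligodendrocyte lineage.

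Mir149 and Mir365-2 were called lower with both compounds, each with 1 read in every DMSO library and 0 in the other 6. The same read number in all 3 controls gives almost no spread on the log scale, from which a small p follows. With voom on all genes with reads, which weighs such low counts less, the lowest adjusted p of the genes was 0.08794, and with NAT it was 0.3294. Single reads repeated across libraries are thus a likely source of these calls. Neither gene reached 10 reads in any library, so a real loss of either microRNA gene was not detectable at this depth.

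Other splits of the same libraries were counted for each result. The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For NAT against DMSO, 2 splits gave at least the real 4 genes, the highest other giving 4 with DMSO replicates 1 and 2 and NAT replicate 1 on a side, and 1 split gave the real 9 lists, the highest other giving 6. Of the 9 other splits 3 called the immediate early list, those with DMSO replicates 1 and 3 on a side and DMSO replicate 2 with 2 NAT libraries on the other, at a lowest adjusted p of 8.198e-10 against the real 1.362e-15. Proliferation was called in 8 of the 9, with 4.295e-12 against the real 5.059e-05, and the oligodendrocyte lineage in 2, with 7.505e-06 against the real 1.25e-04. Astrocyte genes were called in 2, with 4.303e-05 against 6.572e-04, oxidative phosphorylation in 3, with 9.982e-06 against 2.121e-04, and Notch in 1, with 0.0179 against 0.0398. NRF2 targets were called in 2, neuroblast and neuron genes in 1 and fatty acid synthesis in 0, each with a lowest adjusted p above the real one. The lists called in other splits thus also varied between libraries in ways that cross the groups. For P7C3-A20 against DMSO, 1 split gave 3 genes, with 2 as the highest other, and all 10 gave at least the real 0 lists, with 6 as the highest other. For NAT against P7C3-A20, all 10 gave at least the real 0 genes, with 1 as the highest other, and 2 gave the real 5 lists, the other with NAT replicates 1 and 3 and P7C3-A20 replicate 3 on a side. Proliferation was called in 5 of the 9 other splits, at a lowest adjusted p of 0.00467 against the real 2.349e-10, and the oligodendrocyte lineage in 4, at 3.525e-06 against the real 3.127e-09. Immediate early genes were called in 3, at 0.0211 against the real 4.721e-09, NRF2 targets in 1, at 0.0391 against 5.173e-05, and Notch in 0.

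Over all 9 libraries, voom called 348 genes that differed among the 3 groups. Of the 280 possible splits 100 were drawn, and 1 of these 100, the real one, gave as many. Since another split came close, this share alone does not tell the treatments from other structure of the samples. The highest other split gave 344 genes. It kept the P7C3-A20 libraries together and put DMSO replicates 1 and 2 with NAT replicate 1, so a count nearly as large did not need DMSO apart from NAT, which points to a structure of the samples that crosses these groups. With the GC trend removed the real groups gave 111 genes, again 1 of 100, and the highest other split gave 52, with the same DMSO and NAT libraries together, while the split that had given 344 gave 46.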

How the results depend on the processing

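The counts with voom, with a minimum of 10 reads, with the GC correction, with the GC and length correction, with 1 score per list and with thinned reads were chosen only after the results were seen, that is, after seeing the data. Among genes named in the text, 2563 repeated values kept their direction and side of the threshold, 133 passed it where the main test had not, 38 no longer passed and 3 changed sign. These 3 were Nampt between the compounds, at -0.003 with the GC correction, -0.001 with the GC and length correction and -0.011 with voom and the GC correction. The values differ from 0 by less than their error, and the cause was not tested. The Fosb call with NAT was also lost with robust empirical Bayes (adjusted p 0.109), no filter (0.0987) and a pseudocount of 0.1 (0.0507), over a range of 5.68e-09 to 0.130 in all settings. That of C1ql1 with P7C3-A20 was lost with the GC and length correction (0.243), voom with the GC correction (0.122), no filter (0.0915), a minimum of 5 TPM (0.0848), a pseudocount of 0.1 (0.104) and the 6 libraries alone (0.0781).

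Of the counts and covariances, 70 stayed within 1.5 times or 1 SD of the main value and 40 did not. For NAT, P7C3-A20 and their difference, limma called 4, 3 and 0 genes. A minimum of 5 TPM gave 2, 0 and 0, with fewer genes tested, and a pseudocount of 0.1 gave 1, 0 and 0. The 6 libraries compared alone gave 7, 5 and 5, and a minimum log2 fold change of 1 gave 2, 2 and 0. A minimum of 10 reads, which removes the microRNA genes, gave 4, 1 and 0. Voom called 29, 284 and 347 genes, and with the GC correction 58, 41 and 73, of which 29, 28 and 59 were the same genes. Leaving out each library gave 1 to 11, 1 to 10 and 0 to 1 genes. For P7C3-A20, voom called 0 genes without DMSO replicate 1, 8 without DMSO replicate 2, 416 without DMSO replicate 3 and 591, 195 and 248 without P7C3-A20 replicates 1, 2 and 3, and with the GC correction 1, 4, 157, 50, 14 and 148 in that order. For NAT the GC-corrected voom count was 12 to 84, and between the compounds voom called 9 to 834 and, GC-corrected, 1 to 159. The cause of these shifts was not tested beyond the GC correction.

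For NAT, P7C3-A20 and their difference, camera called 9, 0 and 5 lists. With an estimated correlation it called 0, 0 and 0, and 1 score per list gave 2, 0 and 4. The GC correction gave 9, 2 and 5 lists and the GC and length correction 9, 2 and 6, the latter with 8 of the 9 NAT lists kept and fatty acid synthesis lost (adjusted p 0.0667). Leaving out each library gave 7 to 13, 0 to 5 and 5 to 6. The covariance of the responses was 0.00981 with a minimum of 5 TPM and 0.006253 with 10 reads, where fewer weakly expressed genes entered, against simulated values of 0.00648 and 0.00489 for unchanged groups with the same controls. It was 0.01439 to 0.02345 with a library left out, which was not simulated.

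With the replicate number as a block (replicate block), the counts were 3, 7 and 1 genes and 9, 1 and 5 lists, the 1 list for P7C3-A20 being proliferation, lower with an adjusted p of 0.0115, and C1ql1 had an adjusted p of 0.0580. The labels do not say that a number marks a shared batch, and none of the 9 same-numbered pairs had deviations correlated over 0.1 (-0.06 to 0.09, others -0.14 to 0.08), while 5 of 9 libraries correlated best with their own number. With the block, 1691, 2411 and 2423 genes had an unadjusted limma p under 0.05, against 1615, 2194 and 2188 without it. Whether a shared number marks samples that belong together is thus open. Depth limits genes with few reads, and simulated small fold changes were called less often than larger ones in each comparison.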

Other observations

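The voom fit with the GC correction and the genes named in this part were chosen only after the results were seen. With that fit 2 genes were higher and 7 lower with both compounds against DMSO. In 100 simulations of unchanged groups against the same controls none was shared, but each simulated comparison had at most 1 call, and the simulated genes varied independently, so these simulations say little about an overlap that came from the controls. The higher ones were Cacng5 and the prohormone processing gene Cpe, which in the limma test on TPM stood at 0.17 ± 0.04 with NAT and 0.20 ± 0.04 with P7C3-A20. The lower ones were Fosb, Btg2, the Notch effector gene Hes5, Enc1, Amotl2, which acts in Hippo signalling, the phosphatase regulator gene Ppp1r10 and Lars2. In the limma test Enc1 was at -0.20 ± 0.04 with NAT and -0.18 ± 0.04 with P7C3-A20, and Lars2 at -0.77 ± 0.17 and -0.64 ± 0.17. Hes5, Amotl2 and Ppp1r10 were at -0.34 ± 0.07, -0.33 ± 0.07 and -0.22 ± 0.05 with NAT. With P7C3-A20 they were at -0.12 ± 0.07, -0.13 ± 0.07 and -0.14 ± 0.05. None of these lower genes passed in limma with P7C3-A20. The comparisons share the 3 DMSO libraries, so part of this overlap may come from the controls; it also rests on single libraries, since the 58 genes of NAT became 23 without DMSO replicate 1, 25 without DMSO replicate 2, 12 without NAT replicate 2 and 14 without NAT replicate 3, and the 41 of P7C3-A20 became 1 without DMSO replicate 1, 4 without DMSO replicate 2, 157 without DMSO replicate 3, 14 without P7C3-A20 replicate 2 and 148 without P7C3-A20 replicate 3. In the voom fit with the GC correction Igfbp5, which binds insulin-like growth factors, rose with P7C3-A20 (0.25 ± 0.04, adjusted p 0.00753).

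The integrated stress response, p53 and heat shock lists did not pass as lists, but some of their members passed adjusted over the list alone, in both directions. Of the members named here only Btg2 passed over all genes in limma, and only with NAT. Adjustment over a list alone does not account for the number of lists and comparisons. The amino acid transporter genes Slc7a5 and Slc3a2, known targets of the integrated stress response, rose adjusted over the list alone, at 0.21 ± 0.04 and 0.17 ± 0.04 with NAT and 0.18 ± 0.04 and 0.18 ± 0.04 with P7C3-A20, and did not pass over all genes in limma. Shmt2 and Sesn2 of the same list rose adjusted over the list alone with P7C3-A20 (0.15 ± 0.04 and 0.16 ± 0.05). The cell cycle inhibitor gene Cdkn1a, a p53 target, was at 0.19 ± 0.04 with NAT and 0.16 ± 0.04 with P7C3-A20, and the p53 target Gdf15, a stress cytokine gene, at 0.46 ± 0.12 with P7C3-A20, each passing adjusted over the list alone. The co-chaperone gene Bag3 did so as well, at 0.26 ± 0.05 and 0.25 ± 0.05. Members that fell adjusted over the list alone were Ddit4, an inhibitor of mTOR signalling (-0.15 ± 0.04), and the mitochondrial chaperonin gene Hspe1 (-0.16 ± 0.03) with NAT, and the p53 target Btg2 with both compounds. The camera adjusted p of the integrated stress response, p53 and heat shock lists was 0.456, 0.809 and 0.498 for NAT and 0.211, 0.831 and 0.831 for P7C3-A20. With the GC trend removed, the integrated stress response mean for P7C3-A20 went from 0.049 to 0.009, and Slc7a5, Slc3a2, Shmt2, Sesn2, Cdkn1a and Gdf15 no longer passed over their lists with P7C3-A20 (0.10, 0.13, 0.06, 0.06, 0.10 and 0.35), while Bag3 (0.17) and Btg2 (-0.25) did. In voom Bag3 with P7C3-A20 went from an adjusted p of 0.0216 to 0.141 with the GC correction. For NAT, Slc7a5, Slc3a2, Cdkn1a, Bag3, Ddit4, Hspe1 and Btg2 passed over their lists with the GC trend removed as well.

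Some non-coding RNA genes and Lars2 had lower mean values with both compounds, none past the threshold in limma. Voom called Lars2 (adjusted p 3.282e-04), Rmrp (0.0286) and Rpph1 (0.0286) lower with NAT, and Lars2 (0.00787) but not Rmrp (0.105) and Rpph1 (0.173) with P7C3-A20. Rmrp, the RNA of a mitochondrial and nucleolar ribonuclease, held 31.0 ± 4.22 TPM with DMSO, 11.2 ± 6.92 TPM with NAT and 18.2 ± 6.93 TPM with P7C3-A20 (SD, n = 3). Lars2, a leucyl tRNA synthetase gene of mitochondria, held 2295 ± 374, 1344 ± 173 and 1495 ± 375 TPM, and Rpph1 33.3 ± 3.97, 16.4 ± 4.44 and 24.3 ± 2.96 TPM in the same order. Rn45s, whose reads were not recovered and which voom therefore did not test, held 20260 ± 2624, 11200 ± 2414 and 12420 ± 3885 TPM. The Lars2 means ranked as those of Rn45s did. Whether the Lars2 row held only reads of its own transcript was not tested, so its lower values are not read as a change of that gene.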
